A study of Triticum aestivum with 10 samples.

How the data were processed

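RNA was extracted by the authors from whole developing seeds with Trizol and RNeasy columns, labelled with a one-cycle kit and hybridised to the Affymetrix wheat array, 1 array per sample. The deposited values are log2 expression values made by the authors with RMA, which corrects background, sets all arrays to a common distribution of probe signals and summarises the probes of each probe set. The submitters' processing notes name affy and RMA; their versions and settings are not given in the sources used here. The values lay between about 1 and 14 on every array, none was missing, and the medians lay at 4.08 to 4.24. They were used as deposited, with no pseudocount and no further scaling. The table held 1 column per array and no other columns of per-sample values.

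The 10 arrays formed 5 groups of 2 by treatment and time, as labelled. The comparisons, gene lists and other settings to be tried were fixed before the data were examined. Of 61290 probe sets, 111 control probe sets were left out of the tests and 61179 were tested, all of them, with no filter on level. Of the tested probe sets, 1273 had exactly 1 gene symbol, 0 had several and 59906 had none. The symbols stood for 771 genes, 770 of them matched by Entrez identifier in the reference gene table, and 1254 of the 1273 probe sets carried a number beginning with LOC as their symbol. Gene list patterns were therefore applied to the synonyms of the reference table as well, a step chosen after the names had been seen. A gene in a list was represented by its brightest probe set.

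Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, moderated variances with an intensity trend, 5 residual and 3.59 prior degrees of freedom, Benjamini-Hochberg adjustment over the tested probe sets of each contrast and a threshold of 0.05. The 8 planned contrasts were drought against control at 48 and at 72 HAF, their mean and their difference, 3 contrasts between the control times and drought 72 against 48 HAF. The contrast of 72 with 48 HAF over both treatments was added after the data had been seen. Gene lists of at least 3 genes were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 9 lists of a contrast, and also with an estimated correlation and with fry, both from limma. By fry, 0 lists were past the threshold in any contrast after adjustment. Adjusted p-values in the text are those of limma and camera, and permutation p-values are exact.

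Of 23 lists fixed, 9 had 3 or more genes. Their members were 5 dehydrin and LEA genes, 3 hormone genes (all gibberellin 20-oxidases), 3 genes of sucrose and fructan metabolism, 12 of seed storage proteins and grain inhibitors, 3 histones (all H2A), 4 antioxidant, 4 photosynthesis, 5 translation and 5 defence genes. The gene wci stood in both the storage and the defence list, and the storage list also caught GLU1A, which is no storage protein. Heat shock, starch synthesis, cell wall and pollen marker lists had 2 genes each and are described by their values. The other 10 lists had no gene on the annotated part of the array: abscisic acid, cell cycle, MADS-box factors, NAC, MYB, WRKY, bZIP and DREB factors, aquaporins, proline and compatible solutes, proteases and cell death, chromatin and DNA methylation, nucellus and pericarp markers, and endosperm and transfer cell markers.

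The rule for naming genes was set for drought against control at 48 and 72 HAF and for control 48 against 24 and 72 against 48 HAF. It took the 10 largest rises and 10 largest falls among genes with 1 symbol past the threshold whose arrays did not overlap between the groups, and up to 4 members per list. Where fewer than 5 genes passed, it took the 5 annotated genes with the smallest unadjusted p, as was the case in each of the 4 contrasts. Other genes in the text are list members or stand out among the separated probe sets, and were chosen after their values were seen. A probe set counted as separated when all arrays of one side lay above all of the other and the means differed at least 2-fold. Separation was counted for each of the 3 splits of 4 arrays and each of the 35 splits of the 8 arrays of 48 and 72 HAF.

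The limma step was tested on simulated data with 200 of 61179 probe sets changed and array noise as measured in each group. At 2-, 4-, 8- and 16-fold, drought against control at 48 HAF recovered 0, 17.5, 70.5 and 88.5% of the changed probe sets, drought against control at 72 HAF 0, 22, 76.5 and 88.5%, and drought over both times 0, 68.5, 92.5 and 98.5%. Control 48 against 24 HAF recovered 0, 37.5, 73 and 91%, with 99 to 180 unchanged probe sets also called from 4-fold up. Control 72 against 48 HAF recovered 0, 19, 74 and 86%, drought 72 against 48 HAF 0, 27.5, 77 and 89%, and 72 against 48 HAF over both treatments 0, 66.5, 89 and 97%. Noise was drawn independently for each array, while replicate differences in the data correlated between groups at -0.519 to 0.586. For control 48 against 24 HAF, 13.71 to 14.05% of simulated unchanged probe sets had an unadjusted p under 0.05. The data gave 907 of 61179. For 72 against 48 HAF over both treatments the simulated share was 1.63 to 1.715%, and the data gave 2298. The recovery in the data may therefore differ from these percentages. List tests were simulated for drought against control at 72 HAF only, on random probe sets with equal array noise drawn independently for each probe set. There camera called a list of 12 genes shifted by log2 1 in 20 of 20 draws and 0 of 160 lists that were not shifted. Lists of correlated genes were not simulated, so these draws cannot show how often such lists are called falsely. The median 95% interval of a change reached 0.92 (1.90-fold) to each side for a pair of groups, 0.65 (1.57-fold) for contrasts over 4 arrays against 4 and 1.31 (2.48-fold) for the difference between drought effects.

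The other settings were the brighter part of the probe sets (30590, split at the median), cyclic loess, arrays set to one median, no intensity trend, array weights, the replicate number as a block, leaving out probe sets that share sequence between genes (48453 left), each array left out, a fit of only the groups compared, a minimum change of 2-fold, the estimated correlation and the mean over a gene's probe sets. Leaving out the 2 arrays that stand apart, and pairing the arrays with crossed numbers, were added after the data had been seen. Where 1 array of a group was left out, the other was assumed to vary like the other groups. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.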

Results

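Gene expression was measured in developing whole seeds of Redland, a winter wheat cultivar, on 10 Affymetrix wheat arrays. The arrays fell into 5 groups of 2: seeds of watered control plants at 24, 48 and 72 hours after fertilization (HAF), and seeds of plants left without water at 48 and 72 HAF. The study asked how early seed development proceeds with water and without it. The labels call the 2 arrays of a group biological replicates but name no plant or pot, so the p-values measure the spread between these samples. The descriptions give a drought start of 24 HAF in one place and of 48 HAF in another, so seeds taken at 48 HAF had been under drought for 24 hours or had only entered it. Of 61179 tested probe sets, 1273 carried a gene symbol, which stood for 771 genes, and only 102 of these genes had a readable name. All statements on gene groups rest on this small named part of the array, and the 2 arrays per group limit the precision of each value.

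The arrays did not pair up by group. The closest array of each of the 10 arrays lay in another group, and for 5 of the 10 it was of the same time. Across the tested probe sets, the 2 replicates correlated at r = 0.820 for control 24 HAF, 0.986 for control 48 HAF and 0.987 for drought 48 HAF. At 72 HAF they correlated at 0.969 for control and 0.951 for drought. Control 24 HAF replicate 2 stood apart, with r between 0.811 and 0.898 to the other 9 arrays. Its hybridisation control BioB, a bacterial transcript added at hybridisation, read 11.9 on the log2 scale, against 4.01 to 6.97 on the other 9 arrays. Drought 72 HAF replicate 2 lay between, with r between 0.922 and 0.959 to the remaining 8 arrays, which correlated at 0.967 to 0.996 with each other. Profilin, a protein abundant in pollen and in other plant tissues, was the gene LOC543315 of the list of pollen markers, and its log2 level was 12.4 to 12.6 on all 10 arrays.

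**Figure D1:**
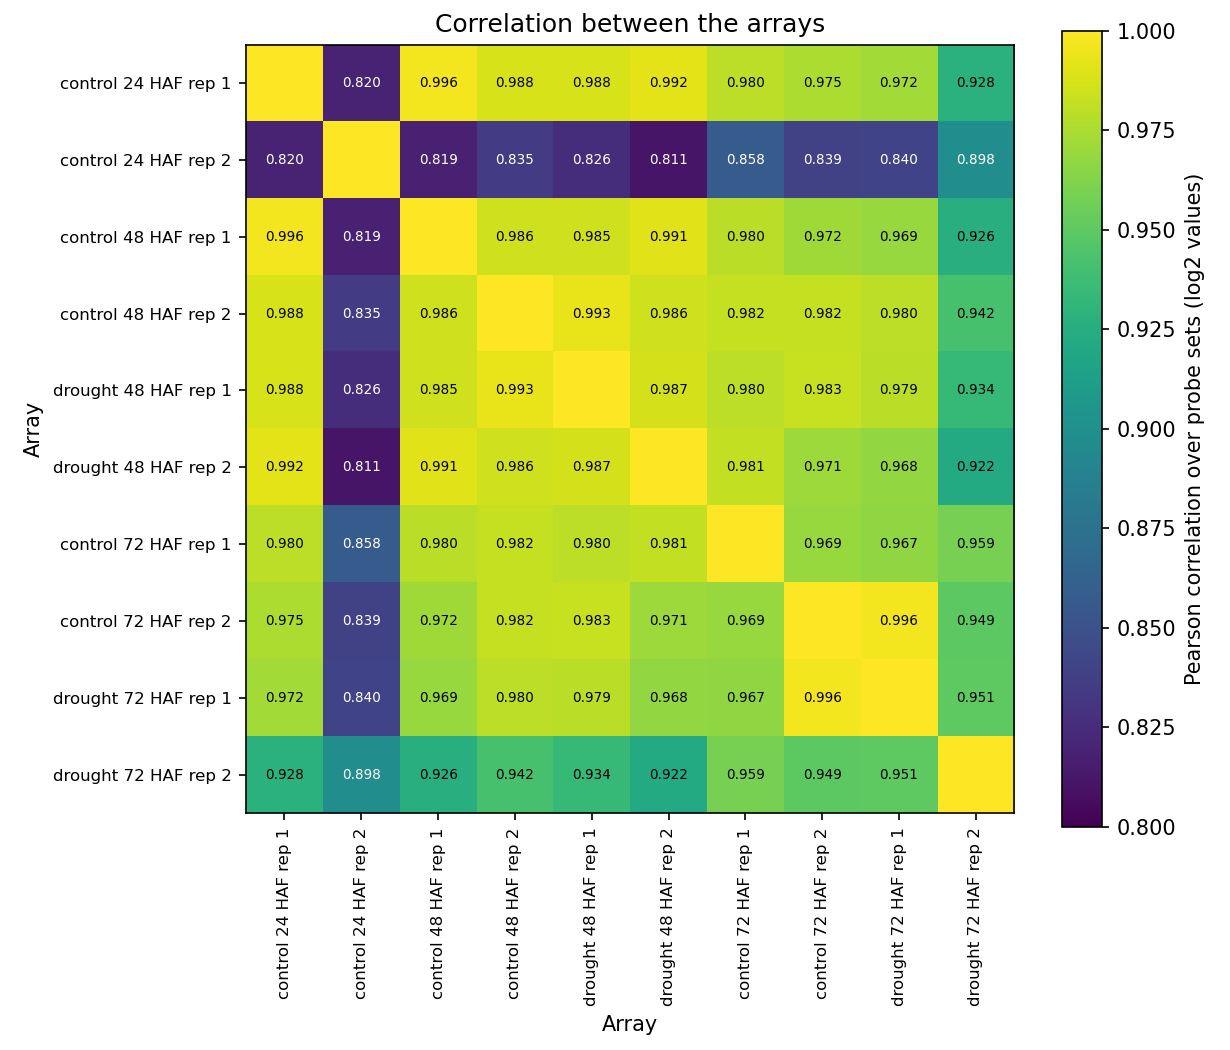
Pearson correlation of log2 values over the tested probe sets for each pair of the 10 arrays (array on each axis, colour from 0.8 to 1). Control 24 HAF replicate 2 correlates at 0.811 to 0.898 with the others, and the closest pairs, such as control 72 HAF replicate 2 with drought 72 HAF replicate 1 at 0.996, cross the groups.

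At 48 HAF, the 5 dehydrin and LEA genes, whose products protect cells during drying, had a mean log2 level of 3.66 ± 0.0060 (SD, n = 2) in drought and 3.62 ± 0.099 (n = 2) in control seeds. Their mean difference was 0.04, with 4 genes higher and 1 lower (camera adjusted p = 0.7). Both group means lay under the medians of the 48 HAF arrays (4.08 to 4.11). Signal over background was not measured, so members with low values may not have been detected. The 3 gibberellin 20-oxidase genes GA20ox1-A, GA20ox1b and GA20ox1d, which encode enzymes of gibberellin synthesis, were the only measured members of the hormone list. By their names they are the A, B and D copies of 1 gene, so a count of 3 of 3 is not one of independent genes. Their mean was 0.26 higher under drought, and 3 of 3 lay higher (camera adjusted p = 0.0888). The 12 seed storage protein and grain inhibitor genes differed by -0.11 on average (adjusted p = 0.7), the 5 defence genes by -0.08 (0.78) and the 4 antioxidant genes by -0.17 (0.685). The 4 photosynthesis genes differed by -0.15 (adjusted p = 0.232), the 5 translation genes by -0.01 (0.896) and the 3 genes of sucrose and fructan metabolism by -0.27 (0.685). The 3 histone H2A genes had a mean of 0.12 and a median of -0.01 (0.785). Leaving out drought 48 HAF replicate 1 brought the gibberellin 20-oxidases (0.33, adjusted p = 0.0192) and the photosynthesis genes (-0.34, adjusted p = 0.00188) past the threshold, and leaving out control 48 HAF replicate 1 the photosynthesis genes (-0.29, adjusted p = 0.0392).

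None of the 61179 probe sets passed limma's adjusted p of 0.05 for drought against control at 48 HAF, and 82 had an unadjusted p under 0.05. In simulated data with the noise measured in each group, 0.238 to 0.276% of unchanged probe sets had one, a larger share than in the data. Uniformly spread p-values would give 3059 such probe sets, and the count in every contrast lay below that number. The annotated genes with the smallest unadjusted p, none past the threshold (limma adjusted p = 1), included LOC543317 at 2.75 ± 0.37 in drought and 3.93 ± 0.48 in control seeds (n = 2 each). LOC606366 lay at 2.37 ± 0.099 against 2.90 ± 0.48, and LOC780602 at 6.82 ± 0.43 against 7.62 ± 0.31. LOC543042 lay at 2.80 ± 0.25 in drought and 2.37 ± 0.041 in control seeds. LOC543085 lay at 2.42 ± 0.020 against 4.13 ± 2.47, a difference of -1.71 that became 0.04 without control 48 HAF replicate 1. Without that array the difference of LOC606366 was -0.20 instead of -0.54. In a fit without control 48 HAF replicate 2, 2 probe sets without a gene name passed (-5.64 and -4.46). The labelled grouping separated 101 probe sets completely by at least 2-fold (11 higher and 90 lower in drought), and the pairing of drought replicate 1 with control replicate 2 against the other 2 arrays separated 1025. With 2 arrays against 2, an exact permutation test cannot give p under 0.333, and chance separates 33.3% of probe sets before the 2-fold limit. Before that limit the labelled grouping separated 19132 of the 61179 probe sets. The median 95% interval of a change reached 0.92 to each side on the log2 scale, or 1.90-fold.

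At 72 HAF, the storage protein genes of the grain were higher in droughted than in watered seeds by the group means, with a very wide spread between the control arrays. The list of 12 seed storage protein and grain inhibitor genes averaged 5.69 ± 0.28 (SD, n = 2) under drought and 4.63 ± 1.67 (n = 2) in controls. The gamma-gliadin LOC543214 was at 8.39 ± 0.32 against 5.16 ± 5.04, and the gliadin LOC543210 at 8.57 ± 0.55 against 6.03 ± 4.12. The 5 defence genes averaged 8.47 ± 0.49 against 7.30 ± 2.28, led by the thionin genes LOC543413 (THI1.3) at 8.51 ± 1.78 against 6.33 ± 4.98 and THI1.2 at 9.50 ± 1.09 against 7.85 ± 4.38. The gene wci, also in the storage list, differed by 1.51, while PR5 (0.42) and LTP3 (0.11) differed by less. On control replicates 1 and 2, THI1.3 read 2.81 and 9.85, much as LOC543214 did (1.60 and 8.73). The storage and defence lists are therefore not independent results. The 3 histone H2A genes averaged 9.93 ± 0.36 against 10.5 ± 0.80.

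By camera, which sets a list against all other probe sets, the storage list rose by 1.06 under drought (10 genes higher and 2 lower, adjusted p = 0.00381) and the defence list by 1.17 (5 of 5 higher, adjusted p = 0.0425). The histone list fell by 0.55 (3 of 3 lower, adjusted p = 0.0491). All 3 calls were lost at adjusted p = 0.444 with an estimated correlation. The control arrays held the spread: the storage list read 3.45 on control 72 HAF replicate 1 and 5.81 on replicate 2, against 5.89 and 5.49 on the drought arrays. Without control replicate 1 the differences were -0.12 for storage, -0.44 for defence and 0.013 for histones (adjusted p = 0.904 for each), and without control replicate 2 they were 2.24, 2.78 and -1.12. Without drought replicate 1 they were 0.86, 0.83 and -0.30, none of them called (adjusted p = 0.729 for each). The defence and histone calls were also lost without control 24 HAF replicate 1 (adjusted p = 0.0764 and 0.0924) or replicate 2 (0.0774 and 0.0927), and with the mean over a gene's probe sets (0.0931 for both).

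Dehydrin and LEA genes were at 3.85 ± 0.32 in drought and 3.79 ± 0.11 in control seeds at 72 HAF (adjusted p = 0.912). Their mean difference was 0.06, while the median of -0.05 and camera's direction were negative. The antioxidant list differed by 0.45 (adjusted p = 0.167), with the gene PER1 (LOC543108) at 5.98 ± 0.87 in drought and 4.69 ± 0.54 in control seeds. The photosynthesis list differed by 0.19 (0.203), the gibberellin 20-oxidases by -0.06 (0.537), the sucrose and fructan genes by -0.34 (0.537) and the translation genes by -0.07 (0.707). Lists past the threshold in fits without 1 array were the antioxidant genes without control 72 HAF replicate 2 (0.85) or drought 72 HAF replicate 2 (0.44), the photosynthesis genes without control 72 HAF replicate 2 (0.32), and the gibberellin 20-oxidases without drought 72 HAF replicate 2 (-0.38). Of single probe sets, none passed limma's adjusted p of 0.05, and 252 had an unadjusted p under 0.05. That is fewer than the 3059 that uniformly spread p-values would give. In simulated data with the noise measured in each group, 3.74 to 3.86% of unchanged probe sets had one, a larger share than in the data. Other annotated genes with the smallest unadjusted p, none past the threshold (limma adjusted p = 1), were LOC542817 at 6.82 ± 0.26 in drought and 5.26 ± 0.21 in controls and LOC543377 at 4.00 ± 0.079 and 3.08 ± 0.38. Next came LOC778398 at 5.37 ± 0.35 and 4.61 ± 0.077, and LOC543016 at 3.53 ± 1.43 and 4.93 ± 0.50. The difference of LOC543016 was -0.39 without drought 72 HAF replicate 2 and -2.41 without replicate 1, and that of PER1 0.67 without replicate 2, against -1.40 and 1.28. The labelled grouping separated 399 probe sets by at least 2-fold (213 higher and 186 lower in drought), while drought replicate 1 with control replicate 2 against the other 2 arrays separated 4868.

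Over both times together, the storage list was 0.48 higher in drought (10 genes higher and 2 lower) and the defence list 0.54 higher (5 of 5 higher), neither past the threshold (camera adjusted p = 0.065 and 0.151). The histone genes differed by -0.22 (0.151), the sucrose and fructan genes by -0.30 (0.357), the antioxidant genes by 0.14 (0.482) and the gibberellin 20-oxidases by 0.10 (0.482). Differences were also small in the dehydrin and LEA genes (0.05, adjusted p = 0.782), the translation genes (-0.04, 0.771) and the photosynthesis genes, at 0.02 with a median of -0.0018 (0.876). Without control 72 HAF replicate 2, storage (1.07), defence (1.35), histone (-0.50) and antioxidant genes (0.34) passed, as did histones without drought 48 HAF replicate 2 (-0.35) and storage without drought 72 HAF replicate 2 (0.58). Storage genes also passed with the replicate number as a block (0.48, adjusted p = 0.0163) and with the mean over a gene's probe sets (0.41, adjusted p = 0.033). None of the probe sets passed limma's threshold for drought over both times, and 68 had an unadjusted p under 0.05. Among the 4 drought arrays and the 4 controls of 48 and 72 HAF, 1 probe set was separated completely by at least 2-fold. It has no gene name and differed by -1.64, or by -0.38 without control 48 HAF replicate 1.

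The drought effect of the storage list was larger at 72 than at 48 HAF by 1.17 on the log2 scale (9 genes higher and 3 lower, camera adjusted p = 0.0207), a call lost at adjusted p = 0.462 with an estimated correlation. The gamma-gliadin LOC543214 went from 1.65 ± 0.083 in control and 1.75 ± 0.076 in drought seeds at 48 HAF to 5.16 ± 5.04 and 8.39 ± 0.32 at 72 HAF. Without control 72 HAF replicate 1 the list's difference was -0.0100 (adjusted p = 0.888), and without control 72 HAF replicate 2 it was 2.35. The call was also lost without drought 72 HAF replicate 1 (0.97, adjusted p = 0.618) and without control 48 HAF replicate 2 (1.07, adjusted p = 0.073). The defence list differed by 1.26 and the photosynthesis list by 0.34 (adjusted p = 0.0875 for both). The gibberellin 20-oxidases differed by -0.31 and the histones by -0.68 (0.0887 for both), the antioxidant list by 0.62 (0.0911) and the translation list by -0.06 (0.864). The dehydrin and LEA list had a mean of 0.02, a median of -0.09 and a negative direction in camera (0.818), and the sucrose and fructan list a mean of -0.07 and a median of 0.24 (0.968). Defence (2.87, 1.60 and 1.46), photosynthesis (0.47, 0.39 and 0.53), histone (-1.24, -0.93 and -0.94), antioxidant (1.02, 0.61 and 0.83) and gibberellin 20-oxidase genes (-0.61, -0.64 and -0.39) passed without control 72 HAF replicate 2, drought 72 HAF replicate 2 or drought 48 HAF replicate 1, in that order. Without control 48 HAF replicate 1, defence (1.37), photosynthesis (0.48), histone (-0.86) and antioxidant genes (0.80) passed. None of the single probe sets passed limma's threshold for this difference, and 227 had an unadjusted p under 0.05. With 0 calls at either time, 0 were shared. Of the 82 and 252 probe sets with an unadjusted p under 0.05, 5 were shared. None of the 5 had a gene name. In drought seeds 1 of them was higher at both times (0.74 and 0.76), and the other 4 were lower at 48 HAF and higher at 72 HAF.

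In watered seeds from 24 to 48 HAF, the gene groups gave no call, and the 24 HAF group held the widest spread. Storage genes averaged 4.55 ± 1.65 (SD, n = 2) at 24 HAF and 3.44 ± 0.13 at 48 HAF, 12 of 12 lower at 48 HAF (-1.12, camera adjusted p = 0.0533). The list passed without control 48 HAF replicate 2 (-1.21, adjusted p = 0.0339). With an unmoved value it passed without either drought 48 HAF array (0.0495 for both), control 72 HAF replicate 1 (0.0047) or replicate 2 (0.00452), and with the replicate number as a block (0.0274). It also passed with the mean over a gene's probe sets (adjusted p = 0.0362). This list read 3.39 on control 24 HAF replicate 1 and 5.72 on replicate 2, the array with the high BioB signal. Fructan exohydrolase genes, whose enzymes break down fructan reserves, were at 9.03 ± 0.82 (LOC780575, 6-FEH) and 8.51 ± 0.39 (LOC543441, 1-FEH) at 48 HAF, and at 6.59 ± 3.94 and 7.34 ± 2.23 at 24 HAF. The lower 24 HAF means came from replicate 2 (3.80 and 5.76), while replicate 1 read 9.38 and 8.91, above the 48 HAF means. Translation genes were at 8.88 ± 0.034 at 48 HAF and 8.35 ± 0.83 at 24 HAF (0.54, adjusted p = 0.225), with 8.93 on control 24 HAF replicate 1 and 7.76 on replicate 2. Defence genes differed by -1.21, sucrose and fructan genes by 0.89, gibberellin 20-oxidases by 0.26, antioxidant genes by 0.24 and photosynthesis genes by 0.09 (adjusted p = 0.514 for each). The defence and the sucrose and fructan differences also rested on control 24 HAF replicate 2 (7.99 and 4.73). Replicate 1 read 5.50 and 6.92, near the 48 HAF means of 5.54 and 6.72. Dehydrin and LEA genes differed by -0.22 and histones by 0.19 (0.634 for both).

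None of the probe sets passed limma's threshold for control 48 against 24 HAF (smallest adjusted p = 0.621), and 907 had an unadjusted p under 0.05. Without control 24 HAF replicate 1, which leaves replicate 2 alone to stand for 24 HAF, 25621 passed (10578 higher and 15043 lower at 48 HAF), and without control 48 HAF replicate 2, 1 passed, without a gene name (5.07). Without control 24 HAF replicate 2, 0 passed. The annotated genes with the smallest unadjusted p, none past the threshold (limma adjusted p = 0.621), were LOC100037541 at 3.13 ± 0.16 at 48 HAF and 4.13 ± 0.47 at 24 HAF, and LOC543270 at 1.59 ± 0.087 and 2.58 ± 0.72. Next came LOC542838 at 4.11 ± 0.16 and 5.19 ± 0.86, and LOC100049056 at 4.04 ± 0.27 and 3.27 ± 0.071. The dehydrin gene Rab15 (LOC543293) lay at 2.03 ± 0.26 and 2.80 ± 0.43 by one probe set, and at 5.08 ± 0.32 and 4.78 ± 0.048 by its brightest, so its probe sets differ in direction. Of these 5 genes, 4 passed the threshold in the fit without control 24 HAF replicate 1 (Rab15 at -1.08, LOC100037541 at -1.33, LOC543270 at -1.50 and LOC542838 at -1.69). Without control 24 HAF replicate 2 the same 4 differed by -0.47, -0.66, -0.49 and -0.47. The labelled grouping separated 2244 probe sets by at least 2-fold, and the other 2 groupings of these 4 arrays separated 7575 and 3295.

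From 48 to 72 HAF, storage and defence genes of watered seeds rose by camera on the strength of 1 of the 2 arrays at 72 HAF. The storage list went from 3.44 ± 0.13 to 4.63 ± 1.67 (1.19, 9 genes higher and 3 lower, adjusted p = 0.000126; adjusted p = 0.539 with an estimated correlation). The defence list went from 5.54 ± 0.16 to 7.30 ± 2.28 (1.76, 4 genes higher and 1 lower, adjusted p = 0.000126; adjusted p = 0.272 with an estimated correlation). The alpha-amylase inhibitor gene LOC542981, which encodes a protein active against insect amylases, went from 4.03 ± 0.62 to 6.07 ± 2.76, and the thionin THI1.3 from 2.63 ± 0.079 to 6.33 ± 4.98. The 3 gibberellin 20-oxidases rose by 0.51 (3 of 3 higher, adjusted p = 0.0036; adjusted p = 0.272 with an estimated correlation), with GA20ox1-A at 3.83 ± 0.15 and 4.60 ± 0.35. GA20ox1d lay at 4.84 ± 0.11 and 5.45 ± 0.69. GA20ox1b lay at 2.68 ± 0.15 and 2.84 ± 0.24, near the lower quartiles of these arrays (2.61 to 2.70). Signal over background was not measured, so the sizes of these differences are uncertain.

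Without control 72 HAF replicate 2, the storage list differed by 0.012 (adjusted p = 0.812) and the defence list by 0.15 (adjusted p = 0.534), and without replicate 1 by 2.37 and 3.36. The gibberellin 20-oxidases rested on the other array, differing by 0.21 without control 72 HAF replicate 1 (adjusted p = 0.278) and by 0.82 without replicate 2. Dehydrin and LEA genes differed by 0.17 (adjusted p = 0.361) and photosynthesis genes by 0.10 (0.549). Histones differed by 0.16, sucrose and fructan genes by -0.33, translation genes by -0.13 and antioxidant genes by -0.09 (0.578 for each). Histones passed without control 72 HAF replicate 2 (0.73, adjusted p = 0.00617). None of the probe sets passed limma's threshold, and 187 had an unadjusted p under 0.05. Without control 48 HAF replicate 2, 2 passed, without gene names (-5.63 and -4.53). The annotated genes with the smallest unadjusted p, none past the threshold (limma adjusted p = 1), were the lipid transfer protein gene LTP3 (LOC543095) at 12.6 ± 0.16 at 72 HAF and 12.1 ± 0.26 at 48 HAF, and LOC543416 at 6.97 ± 0.10 and 5.77 ± 0.30. Next came LOC542918 at 5.26 ± 1.08 and 3.74 ± 0.28, LOC542926 at 4.19 ± 1.21 and 2.45 ± 0.021, and LOC780640 at 4.26 ± 0.21 and 3.61 ± 0.045. Without control 72 HAF replicate 2, LOC542918 differed by 0.76 instead of 1.52 and LOC542926 by 0.89 instead of 1.74. The labelled grouping separated 349 probe sets by at least 2-fold, and the other 2 groupings separated 1327 and 356.

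Between 24 and 72 HAF in watered seeds, the gibberellin 20-oxidases rose by 0.77 (3 of 3 higher, camera adjusted p = 0.0426), from a mean of 3.53 ± 0.42 to 4.30 ± 0.43 (n = 2 each). GA20ox1b lay at 2.59 ± 0.032 and 2.84 ± 0.24, low values for which signal over background was not measured. The call was lost at adjusted p = 0.752 with an estimated correlation, at 0.068 with the replicate number as a block and at 0.114 with the mean over a gene's probe sets. It was also lost without control 24 HAF replicate 1 (1.07, adjusted p = 0.274), control 24 HAF replicate 2 (0.47, adjusted p = 0.0505) or control 72 HAF replicate 1 (0.47, adjusted p = 0.129). The storage list had a mean of 0.08, a median of -0.02 and a negative direction in camera (adjusted p = 0.846), and the dehydrin and LEA list a mean of -0.05 and a positive direction (0.862). The defence list differed by 0.55 and the photosynthesis list by 0.19 (adjusted p = 0.394 for both). The translation list differed by 0.41 (0.353), the histones by 0.35 (0.643), the antioxidant list by 0.15 (0.648) and the sucrose and fructan list by 0.56 (0.71). The storage list passed in opposite directions, at -1.10 without control 72 HAF replicate 2 (adjusted p = 0.00215), 1.25 without control 72 HAF replicate 1 (0.0113) and 1.24 without control 24 HAF replicate 2 (0.000605). Without control 24 HAF replicate 2 the dehydrin and LEA list (0.33, adjusted p = 0.0302) and the defence list (1.80, 0.000605) passed, as did defence without control 72 HAF replicate 1 (2.16, 0.0022) and histones without control 72 HAF replicate 2 (0.92, 0.0118). None of the probe sets passed limma's threshold (smallest adjusted p = 0.728), 1267 had an unadjusted p under 0.05, and 22783 passed in the fit without control 24 HAF replicate 1.

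Under drought, the storage and defence lists rose by camera from 48 to 72 HAF, and here the list means of both arrays at 72 HAF lay above both at 48 HAF. The storage list went from 3.33 ± 0.048 to 5.69 ± 0.28 (SD, n = 2 each), a rise of 2.36 (10 genes higher and 2 lower, camera adjusted p = 1.18e-05; adjusted p = 0.395 with an estimated correlation). Of the 5 gliadins, monomeric storage proteins of wheat endosperm, 3 had the largest differences in the list: LOC543214 was at 1.75 ± 0.076 and 8.39 ± 0.32, LOC543210 at 3.07 ± 0.26 and 8.57 ± 0.55 and LOC543211 at 4.62 ± 0.15 and 9.69 ± 0.74, none of the 3 past limma's threshold. The other gliadins, LOC543212 at 1.92 ± 0.17 and 3.35 ± 0.74 and LOC543385 at 1.49 ± 0.046 and 2.43 ± 0.41, differed by less than the inhibitor LOC542981 at 4.01 ± 0.054 and 7.19 ± 1.27. At 48 HAF, LOC543214, LOC543212 and LOC543385 lay under the lower quartiles of the drought arrays (2.63 and 2.59). Signal over background was not measured, so the sizes and order of these differences are uncertain. The low molecular weight glutenin LOC543213 stood at 5.33 ± 0.047 and 7.32 ± 0.0039. The defence list went from 5.46 ± 0.28 to 8.47 ± 0.49, a rise of 3.01 (5 of 5 higher, adjusted p = 5.5e-05; adjusted p = 0.391 with an estimated correlation), with THI1.3 at 2.89 ± 0.72 and 8.51 ± 1.78.

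The photosynthesis list rose by 0.45 under drought (3 genes higher and 1 lower, adjusted p = 0.0437; adjusted p = 0.395 with an estimated correlation, and 0.0644 with the replicate number as a block), with the photosystem II gene PsbO (LOC543291) at 10.5 ± 0.38 and 11.3 ± 0.036. This call was lost without control 24 HAF replicate 1 (adjusted p = 0.149), control 24 HAF replicate 2 (0.159), drought 48 HAF replicate 2 (0.26, adjusted p = 0.354) or drought 72 HAF replicate 1 (0.40, adjusted p = 0.567). The antioxidant list differed by 0.53 (0.416), the gibberellin 20-oxidases by 0.20, the dehydrin and LEA genes by 0.19 and the sucrose and fructan genes by -0.40 (0.787 for each). The translation genes differed by -0.19 (0.783) and the histones by -0.51 (0.405). Over all probe sets 0 genes were called by limma (smallest adjusted p = 0.953), and 2470 probe sets had an unadjusted p under 0.05. Adjusted over the list alone, 4 defence genes passed (THI1.3, THI1.2, wci and LTP3, adjusted p = 0.044 for each), 0 storage genes, and 1 antioxidant gene, PER1, which rose by 1.64 (adjusted p = 0.0323). The 4 defence calls were lost without either control 48 HAF array or any 1 of the 4 drought arrays (adjusted p = 0.0614 to 0.146). The PER1 call was lost without either control 48 HAF array (0.062 and 0.0622), either drought 48 HAF array (0.0934 and 0.158) or drought 72 HAF replicate 2 (1.03, adjusted p = 0.235). Fitted with only the 4 drought arrays, limma called 91 probe sets, 90 of them higher at 72 HAF. The labelled grouping separated 4699 probe sets by at least 2-fold (1771 higher and 2928 lower at 72 HAF), and the other 2 groupings of these 4 arrays separated 673 and 828. Drought 72 HAF replicate 2 is an array that stands apart, with a narrower spread of values (SD 2.30, against 2.44 and 2.48 on the drought 48 HAF arrays). These counts may rest in part on it.

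A comparison of the 4 arrays at 72 HAF with the 4 at 48 HAF, over both treatments, was added after the arrays had been seen. The storage list rose by 1.78 (10 genes higher and 2 lower, camera adjusted p = 2.67e-06; adjusted p = 0.359 with an estimated correlation), and the defence list by 2.38 (5 of 5 higher, adjusted p = 9.62e-06; adjusted p = 0.3 with an estimated correlation). The defence value was 1.58 without control 72 HAF replicate 2. By limma 0 genes passed over all probe sets, or 6303 probe sets in a setting chosen after the data had been seen (crossed replicate numbers as blocks, control 24 HAF replicate 2 left out). In the fit without blocks, 7 storage and 4 defence genes passed adjusted over the list alone. Among these list calls were LOC543214, which rose by 5.08 ± 1.57 (SE, adjusted p = 0.0359 over the list), LOC542981 by 2.61 ± 0.82 (0.0359), THI1.3 by 4.66 ± 1.38 (0.0219), THI1.2 by 3.90 ± 1.32 (0.0283), wci by 2.60 ± 0.97 (0.0325) and LTP3 by 0.52 ± 0.13 (0.0191). All 7 storage calls, and those of wci and THI1.2 among the defence genes, were lost without any 1 of the 8 arrays other than control 72 HAF replicate 1 (adjusted p = 0.0751 to 0.183 in the storage list and 0.0524 to 0.127 in the defence list). The THI1.3 call was lost without either control 48 HAF array, drought 48 HAF replicate 2 or drought 72 HAF replicate 1, and the LTP3 call without control 48 HAF replicate 1, drought 48 HAF replicate 2 or drought 72 HAF replicate 1 (0.0561 to 0.0904). Without control 72 HAF replicate 2, LOC543214 differed by 3.29, LOC542981 by 1.63, THI1.3 by 2.90 and THI1.2 by 2.36. The rise was not even across the arrays, since control 72 HAF replicate 1 read 3.45 for storage and 5.69 for defence, close to the 48 HAF arrays at 3.30 to 3.53 and 5.26 to 5.66. Photosynthesis genes differed by 0.28 (0.0807) and gibberellin 20-oxidases by 0.36 (0.227). Dehydrin and LEA genes differed by 0.18, antioxidant genes by 0.22, translation genes by -0.16, histones by -0.18 and sucrose and fructan genes by -0.37 (0.541 for each). The photosynthesis genes passed without control 48 HAF replicate 2 (0.35, adjusted p = 0.0252), drought 48 HAF replicate 1 (0.37, 0.00892), control 72 HAF replicate 1 (0.34, 0.014) or drought 72 HAF replicate 2 (0.30, 0.0142).

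The array also carries 3 probe sets for sucrose synthase, an enzyme that splits sucrose in growing seeds, among its wheat control probe sets. The middle probe set was at 9.77 ± 0.62 at 72 HAF and 7.90 ± 0.16 at 48 HAF (SD, n = 4 each), the 5' probe set at 5.74 ± 0.91 and 3.59 ± 0.050, and the 3' probe set at 11.3 ± 0.22 and 10.6 ± 0.065. Unlike the storage genes, the middle probe set was high on control 72 HAF replicate 1 as well, at 9.43 on both control arrays and at 9.54 and 10.7 on the drought arrays. In the exact permutation test each of the 3 had p = 0.0286, the smallest that 4 arrays against 4 can give, and an adjusted p of 0.0649 over the 25 wheat control probe sets, of which 11 reached that p. The others were probe sets of actin, ef1a, gapdh and CYP86-TA, all higher at 72 HAF, and of G-6-PDH, lower (-0.58). The rise was therefore not particular to sucrose synthase, whose probe sets differed by 2.15 (5'), 1.87 (middle) and 0.62 (3'). The 5' difference also exceeded the 3' one for gapdh (0.83 and -0.14), actin (0.75 and 0.16) and G-6-PDH (0.22 and -0.58). It did so too for ef1a (0.58 and 0.24) and ubiquitin (0.22 and -0.10), but not for CYP86-TA (0.78 and 0.85). Whether RNA or labelling differed between the times was not tested with these probe sets, and it stays open.

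**Figure D2:**
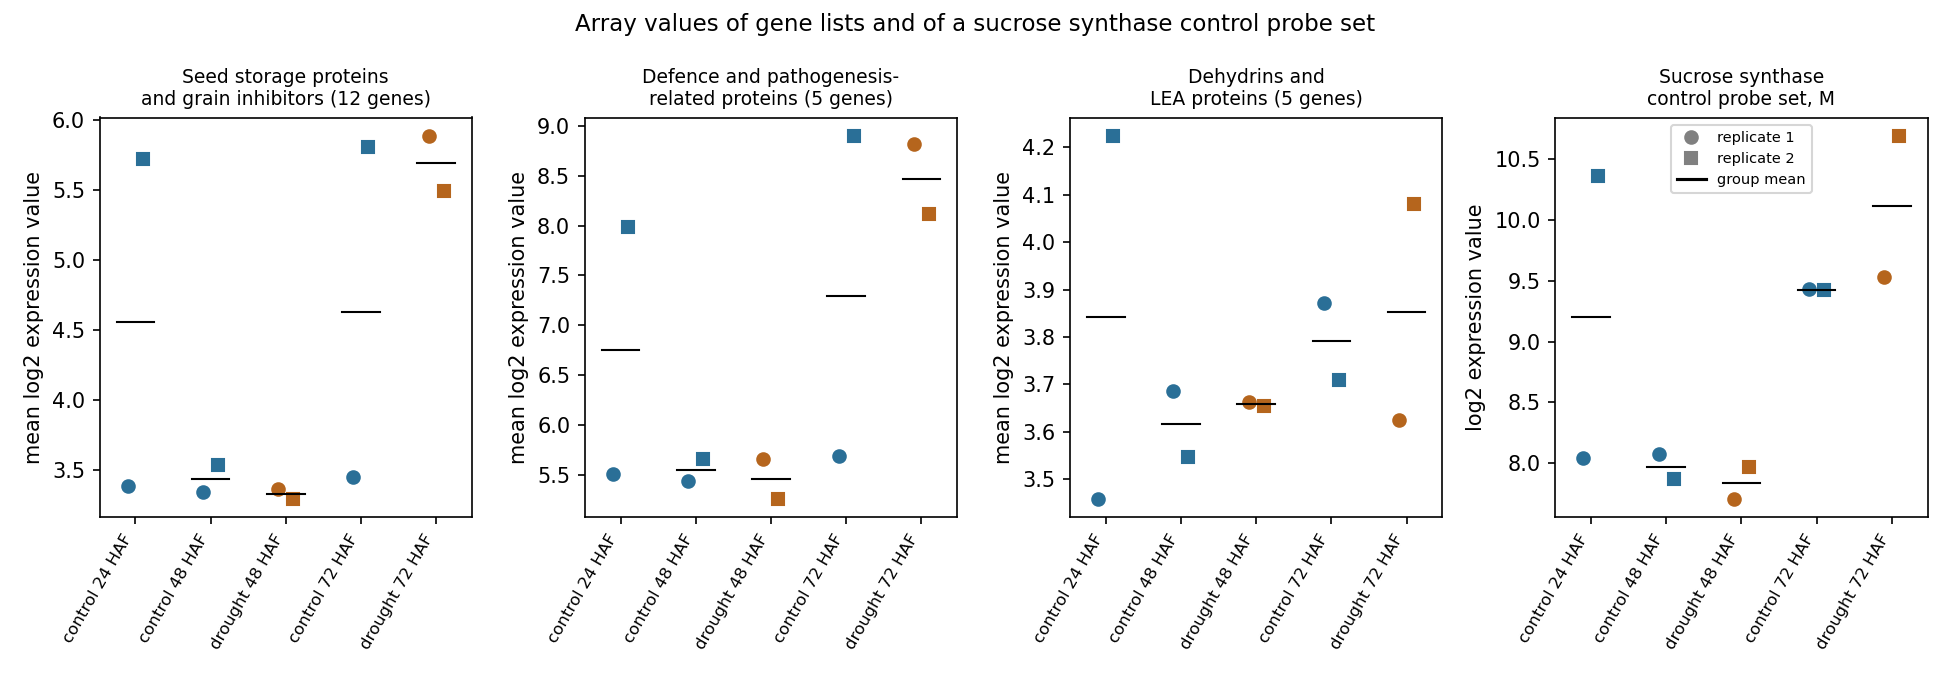
Mean log2 value of 3 gene lists and log2 value of a sucrose synthase control probe set on each array (vertical axes), by group (horizontal axes), with replicate 1 as circles, replicate 2 as squares and the group mean as a line. Storage genes lie at 5.49 to 5.89 on both drought arrays and on 1 of the 2 control arrays at 72 HAF, and at 3.45 on the other, while dehydrin and LEA genes lie at 3.46 to 4.22 throughout.

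Of the single probe sets, 834 separated the 4 arrays at 72 HAF completely from the 4 at 48 HAF by at least 2-fold, 369 higher and 465 lower at 72 HAF. Chance separates 2.86% of probe sets before the 2-fold limit. They covered 28 annotated genes, 18 higher and 10 lower, of which 5 had a readable name. The avenin-like protein gene LOC100125692 was at 7.08 ± 2.58 at 72 HAF and 3.03 ± 0.11 at 48 HAF (SD, n = 4 each), the gene wci (LOC542996) at 8.10 ± 1.52 and 5.50 ± 0.20, and the glutenin LOC543213 at 6.83 ± 0.78 and 5.49 ± 0.19. In these genes control 72 HAF replicate 1 lay only just above the highest 48 HAF array (3.34 against 3.13, 5.83 against 5.66 and 5.69 against 5.68, in that order). Their 2-fold differences therefore came from the other arrays at 72 HAF. The photosystem II gene PsbP (LOC543290) was at 9.23 ± 0.44 and 8.14 ± 0.43 by a probe set other than its brightest. Among those lower at 72 HAF were LOC778385 at 3.32 ± 0.81 and 5.15 ± 0.54, LOC543016 at 4.23 ± 1.19 and 5.81 ± 0.13, and LOC543114 at 5.45 ± 0.60 and 6.86 ± 0.42. The count was 2190 without control 72 HAF replicate 1, 1615 without control 72 HAF replicate 2 and 1292 without drought 72 HAF replicate 1. It was 293 without drought 72 HAF replicate 2 and 516 without probe sets that share sequence between genes. Limma called 0 probe sets for this contrast, with 2298 at an unadjusted p under 0.05, and 2 without control 72 HAF replicate 1 (6.63 and 4.74, without gene names). With crossed numbers as blocks and control 24 HAF replicate 2 left out the calls were 6303 (2172 higher and 4131 lower at 72 HAF). For a single probe set, the smallest two-sided exact permutation p of 4 arrays against 4 is 0.0286.

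**Figure D3:**
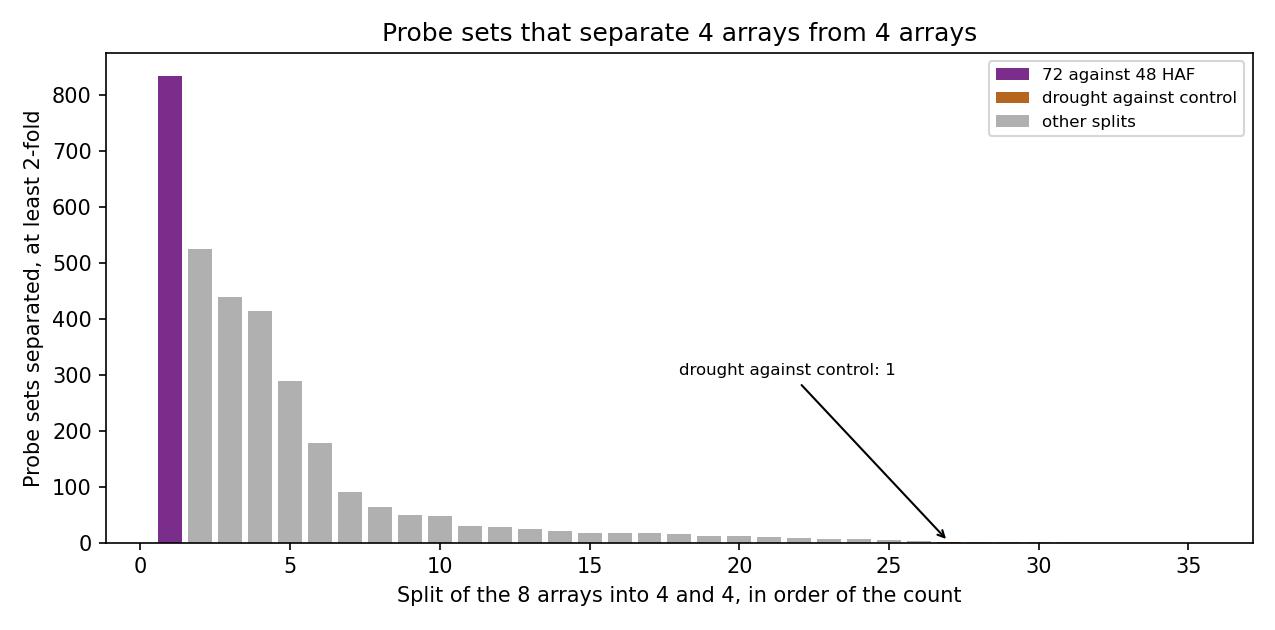
Number of probe sets that separate 4 arrays completely from 4 others by at least 2-fold (vertical axis), for each of the 35 ways to split the 8 arrays of 48 and 72 HAF (horizontal axis, in order of the count). The split of 72 from 48 HAF separates 834 probe sets, the next split 525, and drought from control 1.

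Changes under drought and changes during development were set side by side across the 61179 probe sets, using pairs of contrasts without a common array. The drought effect at 72 HAF correlated with the control change from 24 to 48 HAF at Pearson's r = -0.50 (Spearman's rho -0.43, covariance -0.125), and the drought effect at 48 HAF with the control change from 24 to 72 HAF at r = 0.22 (rho 0.23, covariance 0.0312). Probe sets are not independent replicates, so no p-value is given. The first correlation was 0.21 without control 24 HAF replicate 2 and 0.09 without drought 72 HAF replicate 2, so its sign rested on these 2 arrays. The second was 0.12 without control 48 HAF replicate 1 and 0.13 without control 24 HAF replicate 2.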

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

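The tests of the BioB level, of the replicate differences and of the splits of the 8 arrays were chosen only after the results had been seen; the matched random lists and the positions between 48 and 72 HAF were set before their values were.

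The 5' sucrose synthase control probe set, outside the tested probe sets, differed by 1.34 between drought and control seeds at 72 HAF (6.41 ± 0.67 against 5.07 ± 0.51, SD, n = 2 each), a signal in data the comparisons did not use; this difference was not tested. The middle probe set was at 10.1 ± 0.82 against 9.43 ± 0.0016, with 10.7 on drought 72 HAF replicate 2 and 9.54 on replicate 1, and the 3' probe set at 11.3 ± 0.34 against 11.2 ± 0.016. The drought effect on the storage list differed between 72 and 48 HAF by 1.17 in a test of the difference itself (camera adjusted p = 0.0207; adjusted p = 0.462 with an estimated correlation). This value was -0.0100 without control 72 HAF replicate 1 and 2.35 without replicate 2, and the call was also lost without drought 72 HAF replicate 1 (0.97) or control 48 HAF replicate 2 (1.07).

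Control 24 HAF replicate 2 lay far from the other arrays, with a BioB signal of 11.9 against 5.30 ± 0.977 (SD) on the other 9, as little labelled RNA on the array could give. Its storage list lay 2.34 above that of replicate 1, at percentile 100 of 10000 random lists matched on level (the central 95% ended at 1.01). Random lists hold unrelated probe sets, while the storage genes moved together on single arrays, so this percentile cannot exclude a compressed signal alone. On a scale from 48 HAF (0) to 72 HAF (1), built from 2190 probe sets, its median position was 1.08, against -0.03 for replicate 1, which seeds or RNA of a later stage under this label could give. On a scale built from all 8 arrays of 48 and 72 HAF it was 1.59, near drought 72 HAF replicate 2 at 1.79, the other array that stands apart. The other 72 HAF arrays lay at 0.593 to 0.805. Drought 72 HAF replicate 2 helped build both scales, so these positions cannot tell a later stage from what the 2 arrays share. The differences of control 24 HAF replicate 2 from replicate 1 were 1.52 in the 369 probe sets higher at 72 HAF and -2.94 in the 465 lower ones, outside the ranges of matched sets (-0.447 to -0.200 and -1.25 to -1.01). Drought 72 HAF replicate 2 also helped select these probe sets, so this comparison has the same limit as the positions. Little RNA and a later stage both stay open, and they may hold together.

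The arrays nearest to each other crossed the groups, and control 72 HAF replicate 1 lay near the 48 HAF arrays. Its median position was 0.275 on the scale built without it, above the 48 HAF and first 24 HAF arrays (-0.154 to 0.157) by less than their range of 0.311, so by this bound a swap with control 24 HAF replicate 2 cannot be told apart from a slower seed sample. Against a swap, its middle sucrose synthase probe set read 9.43 (7.71 to 8.07 on the 48 HAF arrays, 8.04 on control 24 HAF replicate 1) and its gibberellin 20-oxidase list 4.60 (3.76 to 4.12 and 3.83), values picked after they were seen. Replicate differences of control and drought seeds correlated at -0.489 at 48 HAF and -0.519 at 72 HAF. Crossed replicate numbers, a shared day of handling and swapped drought and control labels would each give this, and cannot be told apart because the labels name no day or plant.

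The 4 arrays at 72 HAF were separated from the 4 at 48 HAF by 834 probe sets, and the highest of the other splits reached 525. Only the labelled split gave as many (1 of 35), which argues against chance but does not exclude it, as the contrast was added after the arrays had been seen; without drought 72 HAF replicate 2 the count was 293. BioB levels overlapped between the times (5.45 ± 1.08 against 5.29 ± 1.11, SD, n = 4 each; exact permutation p = 0.829), which argues against the share of labelled RNA. In the wheat control probe sets, 5' differences between the times exceeded 3' ones for each transcript with both, except CYP86-TA. A difference in RNA or labelling other than the BioB level therefore stays open. Seed age, which the design names, may be the source, and it stays a hypothesis found and tested on the same arrays, with the day of handling and the state of the RNA untested. Limma called 0 probe sets for this contrast (2298 at an unadjusted p under 0.05), or 6303 with crossed pairing and control 24 HAF replicate 2 left out.

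Limma also called 0 probe sets for drought against control over both times (68 at an unadjusted p under 0.05), and for it and for 72 against 48 HAF 35 of 35 splits gave as many (highest of the others 0), so this comparison of 0 with 0 says nothing on chance.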

How the results depend on the processing

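Leaving out the 2 arrays that stand apart, the crossed pairing, the left-out arrays for genes called over their list alone and all values of 72 against 48 HAF over both treatments were chosen only after the results had been seen. Of 168 counts of limma calls in the 8 planned contrasts under alternatives, 162 were 0, the main count of each. Of 383 values of named genes, 1 had the opposite sign and 4 passed the threshold; of 952 values of lists without a call, 94 had the opposite sign and 57 passed. The storage and defence calls of drought 72 against 48 HAF and of 72 against 48 HAF over both treatments were lost with the estimated correlation, were absent by fry, and were kept under the other settings run on lists (the replicate block, the mean over a gene's probe sets, each array left out and the 2 arrays that stand apart left out). Leaving out an array makes the group smaller, and otherwise the cause was not tested. Signal over background was not measured; in the brighter part of the probe sets limma gave 0 calls in each contrast, and the correlations were 0.28 instead of 0.22 for the drought effect at 48 HAF and -0.60 instead of -0.50 for that at 72 HAF.

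Fitted with only the groups compared, drought 72 against 48 HAF gave 91 calls. With crossed pairing, limma gave 0 calls in each contrast, and 6303 for 72 against 48 HAF over both treatments with control 24 HAF replicate 2 left out as well (2172 higher, 4131 lower). Without probe sets that share sequence, 516 probe sets separated 72 from 48 HAF instead of 834, with fewer probe sets tested.

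Without each array in turn, calls ranged from 0 to 2 for drought against control at 48 HAF, 0 to 25621 for control 48 against 24 HAF, 0 to 2 for control 72 against 48 HAF, 0 to 22783 for control 72 against 24 HAF and 0 to 2 for 72 against 48 HAF over both treatments. The separated probe sets ranged from 293 to 2190. The correlation of the drought effect at 72 HAF with the control change from 24 to 48 HAF ranged from -0.61 to 0.21, turning positive without control 24 HAF replicate 2 (0.21) or drought 72 HAF replicate 2 (0.09), and the other correlation ranged from 0.12 to 0.22.

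For drought at 72 HAF without each array, storage ranged from -0.12 to 2.24, histones from -1.12 to 0.013 and defence from -0.44 to 2.78, with the sign turned without control 72 HAF replicate 1. The difference between the drought effects ranged from -0.0100 to 2.35 for storage. For control 72 against 48 HAF the ranges were 0.21 to 0.82 for hormones, 0.012 to 2.37 for storage and 0.15 to 3.36 for defence. For control 72 against 24 HAF they were 0.47 to 1.07 for hormones, -1.10 to 1.25 for storage and -0.43 to 0.33 for dehydrins and LEA genes. The last list was 0.33 without the 2 arrays that stand apart too, against -0.05. For drought 72 against 48 HAF they were 2.16 to 2.56 for storage, 0.26 to 0.64 for photosynthesis and 2.66 to 3.36 for defence, and over both treatments 1.19 to 2.37 for storage and 1.58 to 3.19 for defence.

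The estimated correlation ended all 13 list calls at unmoved values, since it widens the null spread: at 72 HAF storage 1.06, histones -0.55 and defence 1.17, the difference between drought effects 1.17 for storage, control 72 against 48 HAF hormones 0.51, storage 1.19 and defence 1.76, control 72 against 24 HAF hormones 0.77, drought 72 against 48 HAF storage 2.36, photosynthesis 0.45 and defence 3.01, and over both treatments storage 1.78 and defence 2.38. The mean over a gene's probe sets ended the calls of histones (-0.53) and defence (1.15) at 72 HAF and of hormones in control 72 against 24 HAF (0.55). Without the 2 arrays that stand apart, histones (-0.81, adjusted p = 0.0736) and defence (1.52, adjusted p = 0.0769) at 72 HAF were no longer called. The replicate numbers did not pair the samples, as replicate differences correlated over 0.1 in 3 and under -0.1 in 5 of 10 pairs of groups. With the replicate block, limma gave 0 calls in each contrast, and hormones in control 72 against 24 HAF (0.77, adjusted p = 0.068) and photosynthesis in drought 72 against 48 HAF (0.45, adjusted p = 0.0644) were no longer called.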

Other observations

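The array names 2 starch genes. Granule-bound starch synthase (LOC543395), the enzyme that makes amylose, was at 10.4 ± 0.24 at 24 HAF in controls and between 10.7 and 10.8 in the other 4 groups (SD, n = 2 each). The small subunit of ADP-glucose pyrophosphorylase (LOC543299, AGP-S), which provides the substrate of starch synthesis, was at 9.20 ± 1.16 in controls at 24 HAF (10.02 and 8.38 on the 2 arrays). It was at 10.1 ± 0.064 in control and 10.3 ± 0.11 in drought seeds at 48 HAF, and at 10.5 ± 1.24 and 10.4 ± 1.13 at 72 HAF. The small heat shock protein gene hsp16.9A (LOC543277) was at 3.05 ± 0.59 in control and 3.46 ± 0.54 in drought seeds at 48 HAF, and at 3.91 ± 0.088 and 3.96 ± 0.071 at 72 HAF. The other gene of that list, FKBP70 (LOC543314), was at 10.5 ± 0.034 and 10.6 ± 0.062 at 48 HAF, and at 10.5 ± 0.25 and 9.86 ± 0.95 at 72 HAF.

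Cell wall genes were also high throughout, with XTH, a xyloglucan-modifying enzyme, at 8.63 ± 0.21 to 9.26 ± 0.82 and the lignin methyltransferase COMT1 (LOC543449) at 10.3 ± 0.44 to 10.8 ± 0.34 across the groups. Fructan exohydrolase 6-FEH was at 8.88 ± 0.74 in drought seeds at 48 HAF and 7.30 ± 0.0075 at 72 HAF, and in control seeds at 9.03 ± 0.82 and 8.18 ± 1.30. Among translation genes, RPL9 (LOC543077) was at 6.97 ± 2.18 in controls at 24 HAF and at 8.55 ± 0.062 at 48 HAF. The lower 24 HAF mean came from replicate 2 (5.43), as replicate 1 read 8.51. The LEA gene LOC543476 (LEA1) was at 4.08 ± 0.68 in drought and 3.44 ± 0.025 in control seeds at 72 HAF, not past limma's threshold (adjusted p = 1). It read 3.60 on drought replicate 1 and 4.56 on replicate 2, an array that stands apart.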
